A study of Homo sapiens with 8 samples.

How the data were processed

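Gene expression was measured in P493-6 cells, a human B cell line that carries a MYC gene repressed by tetracycline, so that Myc is high without the drug and low with it. Per the labels, the cells had been infected with an MSCV retrovirus, either empty or carrying Lin28B, an RNA-binding protein that blocks the maturation of let-7 microRNAs. Puromycin at 2 ug/mL then selected the infected cells over 2 weeks, and Myc was lowered with 0.1 ug/mL tetracycline. Every low-Myc sample had the drug and no high-Myc sample did. Effects of Myc and of the drug itself therefore cannot be told apart, and the Myc response below means the difference between these states. Vector and Myc state made 4 groups of 2 arrays each, 8 arrays in all. The labels number the 2 samples of a group and do not say that they came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

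Per the labels' protocols, biotinylated cRNA was prepared from 5 ug of total RNA per sample for Affymetrix arrays. The deposited table holds 1 signal per probe set and array on a linear scale, from 0.0238 to 24295 (arbitrary units). The submitters' processing notes name MAS5, with no version. The signals had been scaled by the authors before they were deposited: on each array the mean signal after removal of the lowest and highest 2% of probe sets was 150.0. Detection calls were not used here. How dim a signal can be told from background is therefore not known. The probe sets of the trp control, which no sample contains, reached 2.65 to 15.8 on the 8 arrays, and the median signal per array was 23.1 to 27.4. The number of arrays limits the precision.

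Probe sets were named from the platform annotation. Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol (19775 genes), 1801 had several and 11721 had none listed. The gene identifiers of 41037 of the 41091 were found in the reference gene table, and no symbol had to be changed. No gene was named from a probe set with several symbols, which leaves some well-known genes not analysed here, NRAS among them.

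From the signals, log2(signal + 6) was computed, where 6 is the rounded 25th percentile of all signals. Every log2 difference and fold below is on that scale, which understates the change of dim genes. Probe sets with a mean signal over all arrays under the median of 25.4 were left out, which left 27307, and each gene was represented by its brightest probe set, giving 11350 genes. Probe sets that disagreed are given for genes of the Lin28B comparisons and for RRP12. In the Myc comparison of empty-vector cells, dim probe sets past the filter moved far less than the one used for PPAT (0.33), GINS2 (0.05), CDK6 (0.33), CD79B (-0.04) and ITGAM (-0.33), and the other probe sets of DICER1 differed by -0.04, -0.49 and 0.23, against -0.32. Among the 4185 genes called between Myc states in empty-vector cells that had several probe sets, 149 had a probe set called the other way.

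Differences were tested with limma 3.58.1 in R 4.3.3, in 1 fit of the 4 group means over all 8 arrays with empirical Bayes moderation and an intensity trend (4 residual and 7.48 prior degrees of freedom). P-values were adjusted over the genes by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05. The 7 comparisons were high against low Myc in each vector and in their mean, Lin28B against empty vector in each Myc state and in their mean, and the interaction. Tests are two-sided. Values of a gene are given as the mean ± SD of the signals of the 2 arrays of a group, and differences as log2 difference ± standard error of the fit.

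Before the data were examined, 30 gene lists were fixed, together with the rule for naming genes. The rule takes MYC and LIN28B, the 8 largest rises and 8 largest falls past the threshold whose arrays do not overlap for the Myc comparison in empty-vector cells and for the mean Lin28B comparison, and 3 of each for the other comparisons. It adds up to 4 called members of each list with the largest change, or up to 2 with the smallest adjusted p where none was called, and let-7 targets, of which HMGA2, IGF2BP1, IGF2BP3, DICER1, CDC34, NRAS and CDK6 are named; 1 other is not reported here. HMGA2 stayed below the filter. Lists were tested with camera, a competitive test that compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 29 lists with at least 5 measured genes. The list of monocyte and macrophage markers had 2 measured genes and was not tested. The 95% interval of a list's mean was taken from the spread of that mean between the 2 arrays of each group.

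The fit was tested on simulated data, 20 sets of 11350 genes with 200 changed genes each. For the mean Lin28B comparison it called 63.9%, 88.1% and 98.7% of the genes changed by 0.5, 1 and 2 (log2), with 9.65 unchanged genes called per set. For Lin28B at high Myc the shares were 41.7%, 78.3% and 93.0%, and at low Myc 41.2%, 78.2% and 92.4%. The noise was drawn independently for each gene. With fewer than 200 changed genes the adjusted threshold becomes stricter, so these shares may be too high for the data. A small number of genes called with Lin28B therefore does not show that few changed by 0.5 or less. Had 200 genes changed as simulated, most of those changed by 1 or 2 would have been called.

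The alternatives were quantile normalization, median scaling, pseudocounts of 1 and 25, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, each probe set by itself, no intensity trend, an added threshold of 1 (log2), the sample number as a block, leaving out each array, the 4 arrays of the 2 groups compared by themselves, and the estimated correlation. Scaling to the poly-A control RNAs was added after the data had been seen. In that scaling the signals of each array were multiplied by 1 factor, so that the mean log2 signal of 24 probe sets for 4 Bacillus subtilis RNAs was the same on every array. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.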

Results

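Tetracycline lowered the MYC signal of empty-vector cells from 13260 ± 513 to 2399 ± 120 (mean ± SD, n = 2 arrays per group). MYC was thus higher at high Myc by 2.46 ± 0.09 (log2 ± SE; 5.52-fold, adjusted p = 5.26e-10). LIN28B, which codes for the RNA-binding protein that blocks let-7 maturation, was higher at high Myc by 5.05 ± 0.23 (33.1-fold; signal 564.5 ± 26.1 against 11.5 ± 4.3, adjusted p = 3.18e-09). The other large rises at high Myc were KISS1R, the kisspeptin receptor (5.30 ± 0.17), CBS, which makes cystathionine from serine and homocysteine (5.15 ± 0.37), SLC19A1, the reduced folate carrier (5.01 ± 0.35), and SCD, a fatty acid desaturase (4.80 ± 0.12). NPW, a neuropeptide gene (4.75 ± 0.37), HPDL, a dioxygenase-like enzyme (4.74 ± 0.20), and MATR3, a nuclear matrix protein (4.73 ± 0.12, from its only probe set with 1 gene symbol), also rose. The largest falls were those of MARCHF1, a ubiquitin ligase that removes class II molecules from the cell surface (-4.80 ± 0.25), MS4A7, a membrane protein of the CD20 family (-4.73 ± 0.21), and IFI27, an interferon-induced gene (-4.66 ± 0.19). CFP, the complement factor properdin (-4.62 ± 0.39), CD1C, which presents lipid antigens (-4.45 ± 0.22), RSAD2, an antiviral enzyme (-4.45 ± 0.23), DHRS9, a retinol dehydrogenase (-4.29 ± 0.43), and DDX60, an antiviral helicase (-4.27 ± 0.10), fell as well. LIN28B, CBS, SLC19A1, NPW, CFP and DHRS9, and TNF, LTA, CCL22, EDN1, VLDLR and ITGAX named further on, had their dimmer group within or below the range of the absent trp control over the 8 arrays (2.65 to 15.8), so that their folds depend on the pseudocount.

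**Figure D1:**
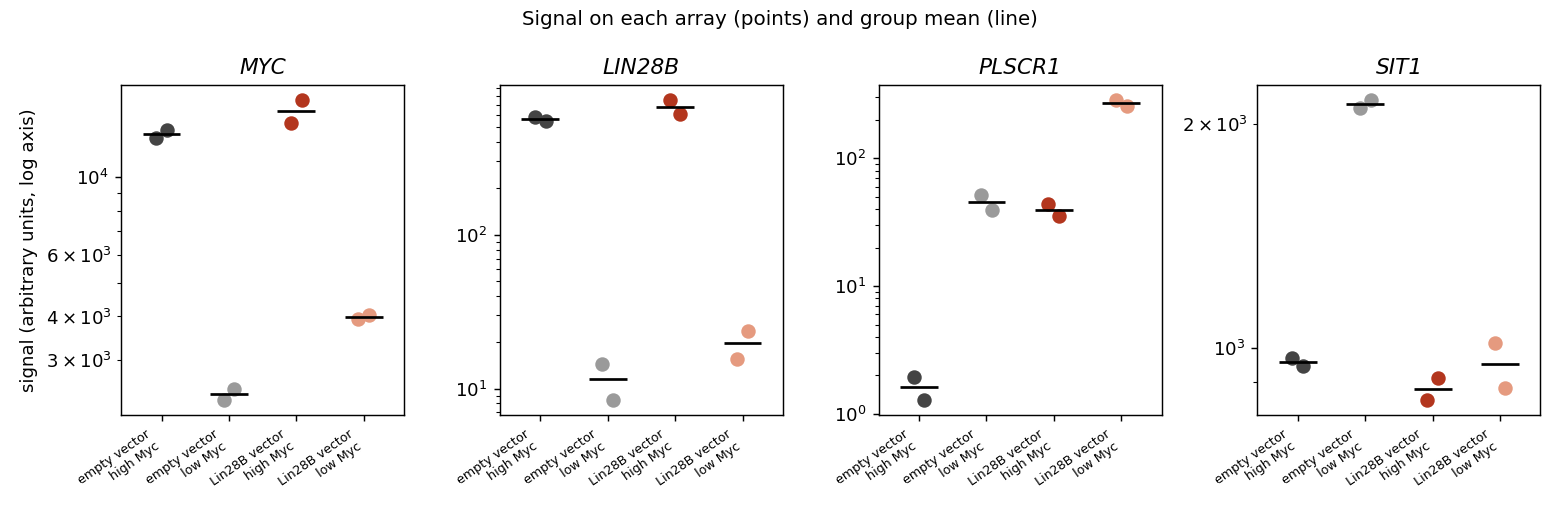
Signal of MYC, LIN28B, PLSCR1 and SIT1 on a log axis in the 4 groups of vector and Myc state. Points are the 2 arrays of a group and the line is their mean; LIN28B was bright only at high Myc, whichever the vector.

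In empty-vector cells 7344 of 11350 genes changed between the Myc states, 3733 higher and 3611 lower at high Myc, and 1906 rose and 1784 fell at least 2-fold. The arrays of the groups did not overlap for 81.1% of the genes, where chance gives 33.3%. The split into higher and lower depends on the scaling. Relative to the poly-A control RNAs, a scaling added after the data had been seen, the median gene was higher at high Myc by 0.83 and 8236 genes changed, 7070 higher and 1166 lower (85.8% higher, against 50.8% in the deposited scaling). Of these 507 were called in the other direction. With median scaling 4099 genes were higher and 3247 lower (55.8% higher). Changes below are relative to the average gene of the deposited scaling; for called lists whose mean changes sign relative to the poly-A controls here or in the mean Lin28B comparison, that mean is given.

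The poly-A controls, bacterial RNAs added to the total RNA before labelling, were brighter at low Myc by 0.84 (log2; 1.79-fold, 24 probe sets, 4 arrays against 4; exact permutation p = 0.0286, the smallest such a test can give), each of dap (0.80), lys (0.80), phe (0.82) and thr (0.93). The hybridization controls, added after labelling, differed by 0.10 (18 probe sets, exact permutation p = 0.486), by 0.19 in empty-vector and 0.003 in Lin28B cells. Array 2 of the Lin28B high-Myc group was the brightest in them (0.336 relative to all arrays). The other high-Myc arrays were the dimmest (-0.203 to -0.151). ACTB had a 3' to 5' ratio of 1.46 to 1.88 at high and 1.31 to 1.37 at low Myc, and GAPDH one of 1.17 to 1.21 and 1.23 to 1.29. The ribosomal RNA probe sets moved in different directions: the 18S 3' signal was 7013 to 12182 at high and 518 to 2106 at low Myc, and the 18S 5' signal 10841 to 13365 and 15611 to 17260. For 28S the 5' signal was 1753 to 8850 and 508 to 1782, and the middle signal 3528 to 4112 and 3631 to 4871. Arrays of the same group had Spearman correlations of 0.908 to 0.920, arrays of the same Myc state and other vector 0.909 to 0.923, and arrays of different Myc states 0.866 to 0.878.

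**Figure D2:**
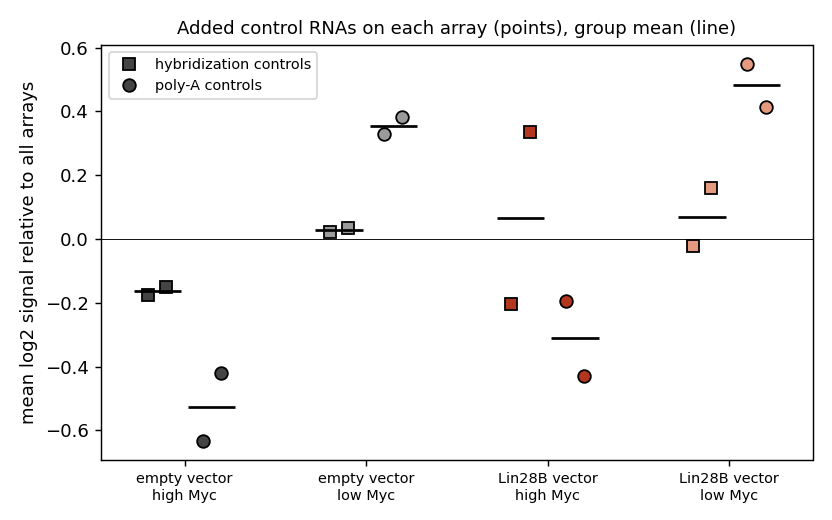
Log2 signal of the hybridization controls (squares) and poly-A controls (circles) on the 8 arrays. The poly-A controls were brighter on the low-Myc arrays by 0.84, while the hybridization controls differed by 0.10.

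Genes of ribosome biogenesis rose at high Myc without exception. The 39 measured rose by 2.14 on average (log2; 95% interval 2.06 to 2.21), among them POLR1A, the large subunit of RNA polymerase I (3.49 ± 0.26), LYAR, a nucleolar protein (3.41 ± 0.12), RRP9 (3.23 ± 0.19) and RRP12 (3.18 ± 0.22), which process ribosomal RNA. A dimmer probe set of RRP12 differed by -1.20. Of 28 established Myc-activated genes 27 rose (mean 2.42), including SLC19A1, FKBP4, a heat shock co-chaperone (3.84 ± 0.14), BCAT1, which starts the breakdown of branched-chain amino acids (3.79 ± 0.09), and CDC25A, a phosphatase that opens the cell cycle (3.75 ± 0.21). Mitochondrial biogenesis genes rose in 24 of 25 cases (mean 1.89), with HSPE1, a chaperonin (2.85 ± 0.10), GRPEL1, an import factor (2.84 ± 0.09), MRPL4, a mitochondrial ribosomal protein (2.82 ± 0.10), and PHB1, a prohibitin (2.73 ± 0.07). Among 21 translation factors 19 rose and WARS1 fell (mean 1.46); VARS1, the valine tRNA ligase (2.71 ± 0.18), and EIF4EBP1, which restrains cap-dependent translation (2.34 ± 0.11), moved most. The genes of the ribosomal proteins stood apart: of 35 measured only RPL14 (0.37 ± 0.09) and RPL3 (0.31 ± 0.10) rose, none did when adjusted over the list alone, and their mean was 0.02 (95% interval -0.33 to 0.36; camera adjusted p = 0.954). RPL3 lost its call without array 2 of the empty-vector high-Myc group or array 1 of the empty-vector low-Myc group, with no filter and with no intensity trend (lowest value over all settings 0.23), and relative to the poly-A controls all 35 rose (mean 0.90). The other lists of this paragraph passed the camera test (adjusted p = 3.9e-16, 1.45e-14, 3.63e-11 and 1.5e-08, in the order named) and again with an estimated correlation (adjusted p = 0.015, 0.0207, 0.0354 and 0.0207).

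**Figure D3:**
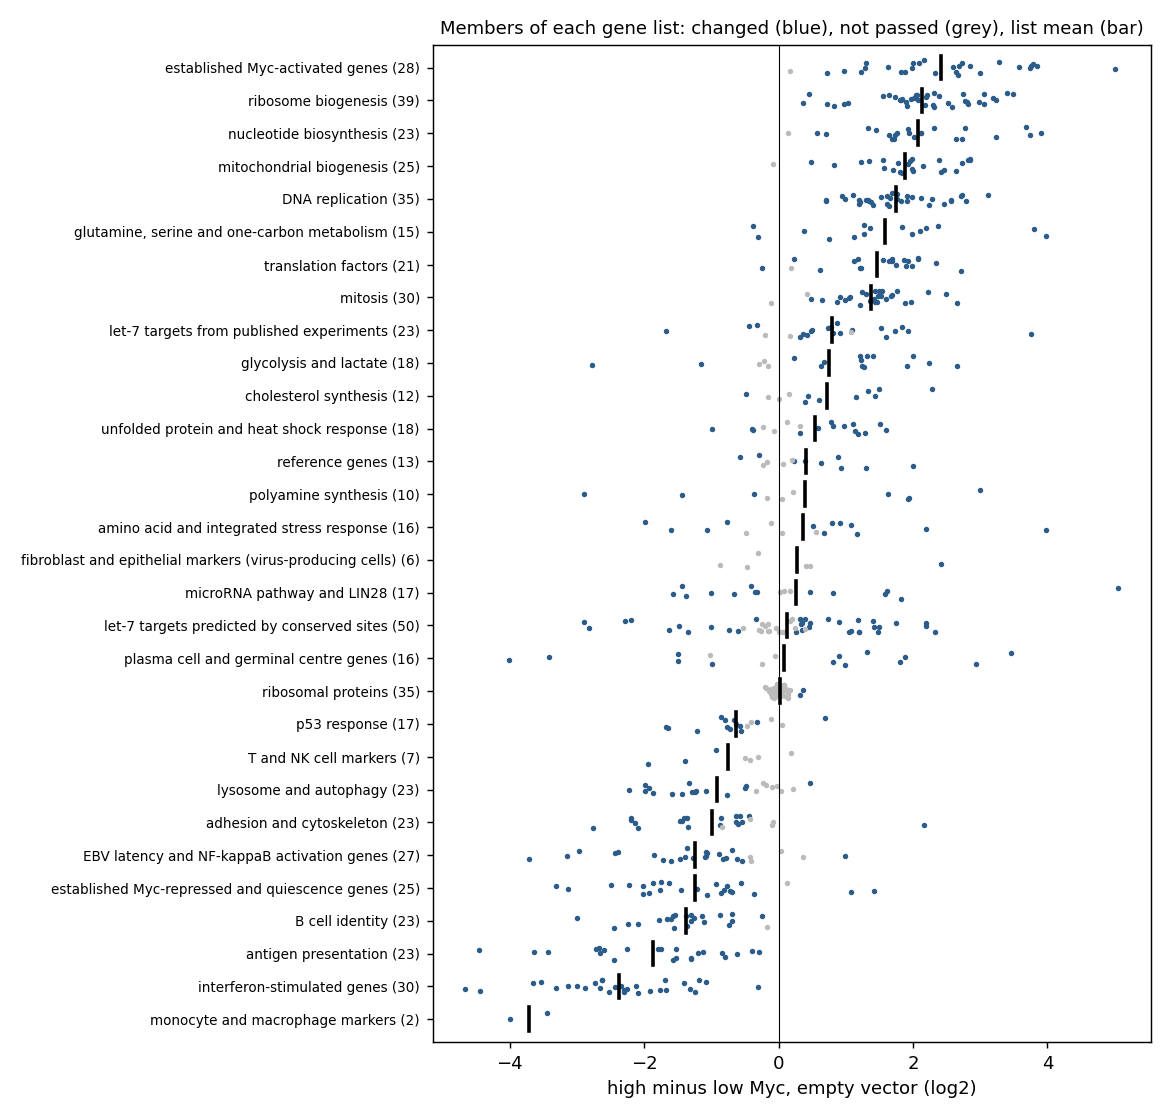
Log2 difference of high against low Myc in empty-vector cells for the members of the gene lists, with blue points for changed genes, grey points for genes that did not pass and a bar at the mean. Ribosome biogenesis (mean 2.14) and interferon-stimulated genes (mean -2.38) lie far apart, and the ribosomal proteins near 0. The highest mean is that of the established Myc-activated genes (2.42), the lowest that of the 2 monocyte markers.

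Genes of DNA synthesis and division were higher at high Myc. All 35 DNA replication genes rose (mean 1.75), with CDC6, which loads the replicative helicase (3.11 ± 0.12), GINS2 (2.79 ± 0.10), MCM4 (2.74 ± 0.22) and MCM10 (2.72 ± 0.17), parts of the replication fork. Of 30 mitosis genes 28 rose (29 when adjusted over the list alone; mean 1.37), with BUB1B (2.66 ± 0.11), MAD2L1 (2.50 ± 0.08) and BUB1 (1.97 ± 0.09) of the spindle checkpoint and BIRC5, survivin (2.22 ± 0.10). Nucleotide biosynthesis rose in 22 of 23 genes (mean 2.08), most in PAICS (3.91 ± 0.09), PFAS (3.69 ± 0.09) and PPAT (3.23 ± 0.10) of purine synthesis and in NME1, a nucleoside diphosphate kinase (3.74 ± 0.09). The 3 lists passed (adjusted p = 1.15e-12, 5.37e-11 and 9.45e-12), also with an estimated correlation (adjusted p = 0.015, 0.015 and 0.0194). Established Myc-repressed and quiescence genes went the other way, with 22 of 25 lower and FOXO3 and MXI1 higher (mean -1.24, adjusted p = 5.03e-06; 0.0207 with an estimated correlation). YPEL3 (-3.31 ± 0.18) and YPEL5 (-3.13 ± 0.08), of the yippee family, TXNIP, a brake on glucose uptake (-2.50 ± 0.10), and NDRG1, a stress gene (-2.23 ± 0.27), fell most. The mean of that list relative to the poly-A controls was -0.38, with 12 lower and 4 higher.

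Enzymes of carbon metabolism rose, with exceptions. In glutamine, serine and one-carbon metabolism 13 of 15 genes rose and 2 fell (mean 1.58, adjusted p = 2.65e-05), led by PSAT1 (3.98 ± 0.09) and PHGDH (2.37 ± 0.11) of serine synthesis, SLC7A5, an amino acid transporter (3.80 ± 0.10), and ASNS, asparagine synthetase (2.19 ± 0.16). With an estimated correlation the adjusted p was 0.0989. In glycolysis and lactate 13 of 18 rose and 2 fell, or 3 when adjusted over the list alone (mean 0.74, adjusted p = 0.00179; 0.241 with an estimated correlation). PFKM, a phosphofructokinase (2.65 ± 0.10), GPI, which isomerizes glucose phosphate (2.24 ± 0.09), and LDHA, which makes lactate (2.00 ± 0.08), rose, while the glucose transporter SLC2A3 fell (-2.78 ± 0.18). Cholesterol synthesis rose in 8 of 12 genes, with DHCR7 (2.28 ± 0.14), HMGCS1 (1.49 ± 0.15), INSIG1 (1.43 ± 0.15) and FDPS (1.33 ± 0.08), and its regulator SREBF2 fell (mean 0.72, adjusted p = 0.0208; 0.0989 with an estimated correlation). In the unfolded protein and heat shock response 11 of 18 rose and 3 fell (mean 0.54, adjusted p = 0.0181; 0.0989 with an estimated correlation), with the chaperone genes HSPH1 (1.60 ± 0.07), SDF2L1 (1.51 ± 0.10), HSP90B1 (1.29 ± 0.09) and HYOU1 (1.18 ± 0.10). The amino acid and integrated stress response did not pass as a list (mean 0.37, adjusted p = 0.215): 8 of 16 rose, PSAT1 and ASNS among them, and 4 fell, among them VLDLR, a lipoprotein receptor (-1.98 ± 0.46), and PPP1R15A, which restarts translation after stress (-1.60 ± 0.17).

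The genes of 4 immune lists were lower at high Myc. All 30 measured interferon-stimulated genes fell (mean -2.38, 95% interval -2.47 to -2.28, adjusted p = 8.18e-16; 0.0207 with an estimated correlation), including IFI27, RSAD2, OAS3, which senses double-stranded RNA (-3.66 ± 0.20), and IFI44 (-3.54 ± 0.14). All 23 antigen presentation genes fell (mean -1.87, adjusted p = 9.2e-12; 0.0656 with an estimated correlation), with CD1C and with HLA-DMB (-3.64 ± 0.09), HLA-DOB (-3.44 ± 0.17) and HLA-DOA (-2.71 ± 0.10), which load peptides on class II molecules or control the loading. B cell identity genes fell in 22 of 23 cases (mean -1.38, adjusted p = 3.54e-10; 0.0207 with an estimated correlation). CD72, an inhibitory receptor (-3.01 ± 0.08), CD37, a tetraspanin (-2.45 ± 0.09), CD24, a surface glycoprotein (-2.24 ± 0.08), and CD79B, the signalling chain of the B cell receptor (-2.10 ± 0.08), fell most. Of 27 genes of EBV latency and NF-kappaB activation 22 fell and IRF4 rose (mean -1.24, adjusted p = 8.54e-06; 0.0207 with an estimated correlation), with the cytokine genes TNF (-3.71 ± 0.34), LTA (-3.15 ± 0.49) and CCL22 (-2.97 ± 0.46) and with BCL2A1, which blocks apoptosis (-2.44 ± 0.17). In the poly-A scaling the means of these lists were -1.51, -0.99, -0.51 and -0.41. Of their genes 27, 16, 15 and 11 fell, and 1, 2, 2 and 3 rose.

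The p53 response fell in 12 of 17 genes, or 13 when adjusted over the list alone, and AEN rose (mean -0.63, adjusted p = 0.00179; 0.0502 with an estimated correlation). FAS, a death receptor (-1.67 ± 0.11), ZMAT3, an RNA-binding protein (-1.64 ± 0.10), SESN1, a restraint on mTOR (-1.21 ± 0.11), and DDB2, a DNA damage sensor (-0.86 ± 0.08), moved most. Lysosome and autophagy genes fell in 15 of 23 cases and GLA rose (mean -0.92, adjusted p = 0.000254; 0.058 with an estimated correlation), with WIPI1 of the autophagosome (-2.22 ± 0.20), the proteases CTSZ (-1.99 ± 0.18) and TPP1 (-1.99 ± 0.13), and TFEB, the master regulator of lysosomal genes (-1.93 ± 0.13). In the poly-A scaling the means of both lists were 0.23 (3 higher and 2 lower) and -0.06 (7 higher and 9 lower), DDB2 differed by 0.02, and SESN1 by -0.34, which no longer passed.

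Of 23 let-7 targets from published experiments 17 were higher and 3 lower at high Myc, or 19 higher when adjusted over the list alone (mean 0.79, 95% interval 0.71 to 0.88, adjusted p = 0.0021; 0.0502 with an estimated correlation). CDC25A, RRM1 (1.92 ± 0.08) and RRM2 (1.73 ± 0.08), which make deoxynucleotides, and CDK6, a kinase of the early cell cycle (1.84 ± 0.14), rose, and FAS, DICER1 and TGFBR1 fell. Predicted let-7 targets with conserved sites were mixed in the deposited scaling, 23 of 50 higher and 11 lower (mean 0.13, adjusted p = 0.3). Relative to the poly-A controls 39 of these were higher and 6 lower (mean 0.97). Of the published targets 22 were then higher and 1 lower (mean 1.65). EDN1, endothelin (-2.89 ± 0.38), CPEB4, a regulator of translation (-2.82 ± 0.23), and PLEKHO1 (-2.28 ± 0.09) fell, and SLC5A6, a vitamin transporter (2.32 ± 0.13), rose. In the microRNA pathway 6 of 17 genes rose and 8 fell (mean 0.26, adjusted p = 0.954), and relative to the poly-A controls 11 rose and 3 fell (mean 1.12). Besides LIN28B the rises were largest for PRKRA, a Dicer partner (1.82 ± 0.12), and for XPO5 (1.61 ± 0.10) and RAN (1.58 ± 0.08), which carry microRNA precursors out of the nucleus.

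In cells with the Lin28B vector MYC was higher at high Myc by 1.95 ± 0.09 (3.86-fold; signal 15440 ± 1651 against 3990 ± 63) and LIN28B by 4.75 ± 0.23. KISS1R (5.21), SCD (5.12) and CBS (4.93) rose most, and DDX60 (-5.03), MS4A7 (-5.02) and DHRS9 (32.1-fold) fell most. The high-Myc signal of DHRS9 (5.78 ± 1.93) lay below the absent control, so that its fold and rank depend on the pseudocount. Over the settings its log2 difference ran from -5.80 to -3.68. In 4 of the lists 39 of 39 ribosome biogenesis genes rose (mean 2.09), 35 of 35 DNA replication genes rose (1.78), 29 of 30 interferon-stimulated genes fell (-2.41) and 23 of 23 antigen presentation genes fell (-1.93). The let-7 targets from published experiments had a mean of 0.82, 17 higher and 4 lower (adjusted p = 0.0017; 0.0464 with an estimated correlation). In all 7389 genes changed, 3725 higher and 3664 lower, and relative to the poly-A controls, where the median gene was higher by 0.74, 7894 changed, 6581 higher and 1313 lower. Of 29 lists tested 20 were called and 14 with an estimated correlation, against 20 and 12 in empty-vector cells.

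The Myc response was nearly the same with both vectors. The log2 differences of the 11350 genes had a Pearson correlation of 0.955 (Spearman 0.941), a slope of 0.979 and the same sign in 89.8%; genes are not independent replicates, so no p-value is given. Of the genes called in each vector 3386 rose in both and 3230 fell in both, where lists drawn independently would share 1225 and 1166, and 3 were called in opposite directions. Averaged over both vectors 8334 genes changed, 4158 higher and 4176 lower, with KISS1R, CBS and SCD at the top and MS4A7, MARCHF1 and DDX60 at the bottom. Relative to the poly-A controls, with a shift of 0.78, 9003 changed, 7528 higher and 1475 lower.

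**Figure D4:**
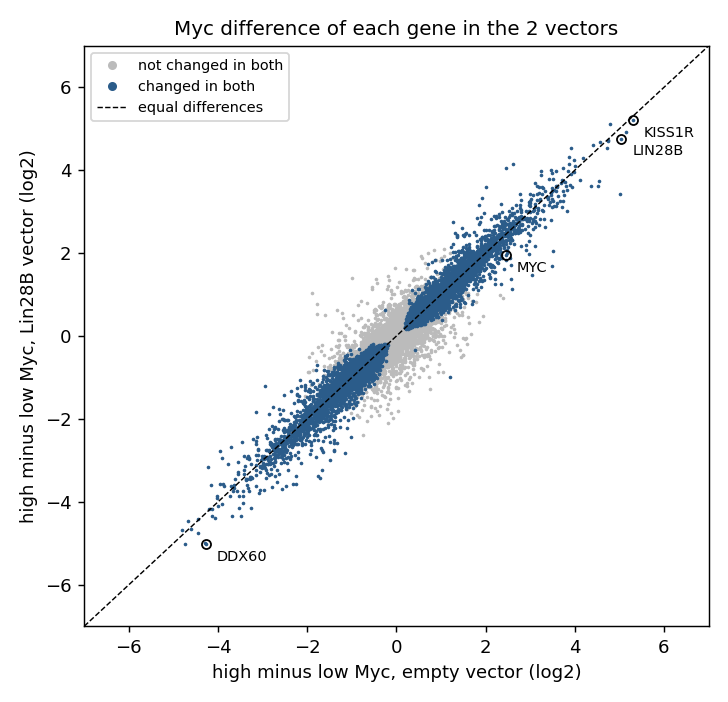
Log2 difference of high against low Myc for 11350 genes, in empty-vector cells (horizontal) and in cells with the Lin28B vector (vertical), with genes changed in both in blue. The points lie along the diagonal (Pearson r 0.955).

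Between Lin28B and empty vector 24 genes passed the test. PLSCR1, an interferon-induced scramblase of membrane lipids, was higher with Lin28B by 2.50 ± 0.21 on average over both Myc states (5.66-fold, adjusted p = 0.00119; 4 arrays against 4). Its signal was 1.63 ± 0.47 with empty vector and 39.6 ± 6.1 with Lin28B at high Myc, and 45.7 ± 8.6 and 270 ± 22 at low Myc. The first of these lay below the absent trp control of its arrays (5.30 and 11.9). The fold therefore depends on the pseudocount (2.50 became 1.67 to 3.25 over the settings). A dimmer probe set of PLSCR1 differed by 0.05 at high and 2.42 at low Myc. LMBR1, a membrane receptor gene (0.94 ± 0.10, adjusted p = 0.00278), MYL4, a myosin light chain (0.55 ± 0.09), RELCH, a cholesterol transport factor (0.52 ± 0.09), NPM3, a nucleolar chaperone (0.51 ± 0.09), QPRT, of NAD synthesis (0.50 ± 0.07), and MYC itself (0.47 ± 0.06, adjusted p = 0.00963) were higher too. The lower genes were led by PITX1, a homeobox gene (-1.96 ± 0.34; -2.45 to -1.23 over the settings, from a dim signal of 16.4 and 10.1 with Lin28B), DYNLT3, a dynein light chain (-1.61 ± 0.20), and PTGER4, a prostaglandin receptor (-1.21 ± 0.20). Others were CALHM6, a channel subunit (-1.15 ± 0.18), KLHL14 (-0.91 ± 0.12), RFTN1, a lipid raft protein of B cells (-0.88 ± 0.12), CD69, an activation marker (-0.71 ± 0.08), and SIT1, an adaptor that dampens antigen receptor signals (-0.64 ± 0.06). Of the 11350 genes 7 were higher and 17 lower, and 1047 had an unadjusted p under 0.05 in limma, where 568 are expected by chance. Arrays of the vectors did not overlap for 9.28% of the genes, where chance gives 5.56%. The count was 12 without either array of the empty-vector high-Myc group, and 6 and 3 without array 1 or 2 of the empty-vector low-Myc group. It was 10 without array 1 of the Lin28B high-Myc group, and 7 and 10 without array 1 or 2 of the Lin28B low-Myc group. Relative to the poly-A controls, with a median shift of -0.17, it was 109, 4 higher and 105 lower. PLSCR1 kept its call in the 17 settings that include it. MYC lost it without array 1 of the empty-vector high-Myc group, without any of the 4 low-Myc arrays, with no intensity trend and with poly-A scaling (0.30 to 0.53 over all settings). LMBR1 and SIT1 kept theirs without each array, CD69 without all but array 2 of the empty-vector low-Myc group, and each other gene named lost it without 2 to 8 of the arrays. With no intensity trend 2 genes passed, and LMBR1, SIT1 and CD69 were not among them; LMBR1 also lost its call with the mean of probe sets.

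The arrays gave no check of the Lin28B vector. The only LIN28B probe set was higher with the Lin28B vector by 0.26 ± 0.23 at high Myc (adjusted p = 0.92) and 0.56 ± 0.23 at low Myc (adjusted p = 0.558), and its low-Myc signal stayed at 19.7 ± 5.9 against 11.5 ± 4.3 in empty-vector cells. The let-7 targets named beforehand did not pass in the mean over both Myc states: IGF2BP1 (0.06 ± 0.10) and IGF2BP3 (0.12 ± 0.06), which bind and stabilize mRNAs, DICER1, which cuts microRNA precursors (-0.05 ± 0.05), CDC34, a ubiquitin-conjugating enzyme (0.01 ± 0.09), and CDK6 (0.09 ± 0.10), with adjusted p from 0.559 to 0.985. The 23 let-7 targets from published experiments had a mean of -0.03 (95% interval -0.09 to 0.03, adjusted p = 0.429) and the 50 predicted targets one of 0.02 (-0.05 to 0.10, adjusted p = 0.429), and no gene of either list passed in the deposited scaling; adjusted over the list alone, 1 predicted target fell. At high Myc the means were -0.02 and -0.01, and at low Myc -0.04 (-0.13 to 0.04) and 0.05 (-0.05 to 0.16). In the poly-A scaling, where the median gene shifts by -0.17, the means over both Myc states were -0.20 and -0.14, and at low Myc, with a shift of -0.12, they were -0.17 and -0.07.

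**Figure D5:**
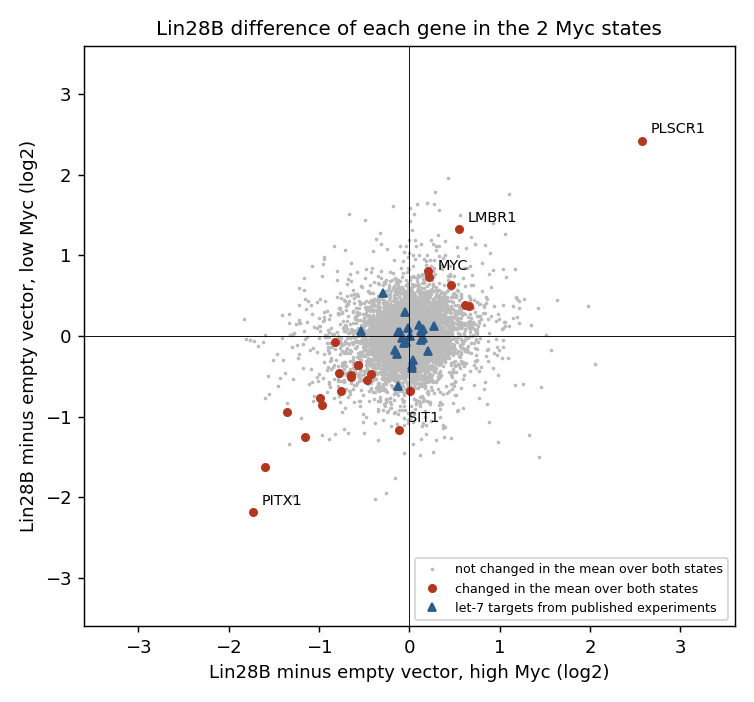
Log2 difference of Lin28B against empty vector at high Myc (horizontal) and at low Myc (vertical), with the 24 genes called in the mean in red and the let-7 targets from published experiments as blue triangles. The triangles gather around 0 and the correlation over all genes is 0.141.

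Small shifts of whole lists with the Lin28B vector did not hold with an estimated correlation. Genes of the ribosomal proteins had a mean of 0.11 (95% interval -0.13 to 0.36, adjusted p = 3.2e-09; 0.558 with an estimated correlation), the p53 response 0.11 (7.15e-05; 0.123), ribosome biogenesis 0.07 (0.0168; 0.323), established Myc-activated genes 0.07 (0.0168; 0.447) and mitochondrial biogenesis 0.06 (0.00943; 0.447). The same means relative to the poly-A controls were -0.06, -0.06, -0.10, -0.10 and -0.11. Mitosis genes had a mean of -0.11 (7.34e-07; 0.1), DNA replication -0.09 (0.00412; 0.157), EBV latency and NF-kappaB genes -0.08 (0.0211; 0.271), B cell identity genes -0.07 (0.0264; 0.447) and T and NK cell markers -0.32 (0.0211; 0.529). Of their genes only IKZF3, a lymphoid transcription factor, passed (-0.45 ± 0.07, adjusted p = 0.0263), while its other probe sets differed by 0.03 and 0.14. IKZF3 lost its call with the mean of probe sets, with no intensity trend and without 6 of the 8 arrays (-0.62 to -0.09 over all settings). CDKN1A (0.27, adjusted p = 0.12) and SESN1 (0.36, adjusted p = 0.145) of the p53 response did not pass, but 4 of its 17 genes did when adjusted over the list alone.

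At high Myc PLSCR1 was higher with Lin28B by 2.58 ± 0.30 (adjusted p = 0.0195; 1.28 to 3.96 over the settings, since its empty-vector signal lay below the absent control, and 0.05 in its other probe set). DDX60 (-0.83 ± 0.10, adjusted p = 0.0195) and MARCKS, a membrane-bound actin regulator (-0.78 ± 0.11, adjusted p = 0.0437), were lower. These 3 were all that passed, with 724 genes at an unadjusted p under 0.05 in limma and 568 expected by chance. MYC differed by 0.22 ± 0.09 (adjusted p = 0.715). The count was 7 without either array of the Lin28B high-Myc group, 1 without array 1 of the empty-vector high-Myc group and 0 without any other array. It was 73 relative to the poly-A controls, 2 higher and 71 lower, with a median shift of -0.21. PLSCR1 lost its call with a pseudocount at the median, with no filter and with the mean of probe sets. Among the fits without an array, it kept it only without array 2 of the Lin28B high-Myc group, DDX60 only without either array of that group (-1.05 to -0.67 over all settings), and MARCKS in none (-1.01 to -0.69). With a pseudocount at the median and with no intensity trend DDX60 and MARCKS lost theirs. MARCKS also lost its call with quantile normalization, with either other filter, with the mean of probe sets and with the sample number as a block. Of the lists 9 were called and 0 with an estimated correlation, the B cell identity genes among them (-0.12, adjusted p = 0.00134; 0.257 with an estimated correlation).

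At low Myc MYC was higher with the Lin28B vector by 0.73 ± 0.09 (1.66-fold, adjusted p = 0.00803), from a signal of 2399 ± 120 to 3990 ± 63. PLSCR1 (2.43 ± 0.30, adjusted p = 0.0115) and LMBR1 (1.32 ± 0.14, adjusted p = 0.00419) were higher. SIT1 (-1.16 ± 0.09, adjusted p = 0.000251), IGFBP2, which binds insulin-like growth factors (-1.04 ± 0.13, adjusted p = 0.0117), and CAMK1D, a calcium-dependent kinase (-0.69 ± 0.08, adjusted p = 0.00616), were lower. A dimmer probe set of CAMK1D differed by -0.17, and the least responsive one of LMBR1 by -0.05. These 6 genes were all that passed, with 919 at an unadjusted p under 0.05 in limma and 568 expected by chance. Without array 2 of the empty-vector low-Myc group 3 passed and without array 2 of the Lin28B low-Myc group 2, and MYC (0.61 to 0.78 over all settings) and PLSCR1 (2.07 to 2.60) lost their call without any of the 4 low-Myc arrays. IGFBP2 and CAMK1D lost theirs without 3 of these arrays and LMBR1 without 2, while SIT1 kept its call without each array. With no intensity trend SIT1, MYC, LMBR1, IGFBP2 and CAMK1D lost theirs, and MYC also with poly-A scaling. With the mean of probe sets PLSCR1, LMBR1 and CAMK1D lost theirs, and PLSCR1 also with a pseudocount of 1 and with no filter. Relative to the poly-A controls 21 passed, 6 higher and 15 lower, with a median shift of -0.12. Of the lists 4 were called and 0 with an estimated correlation, the p53 response among them (0.20, adjusted p = 0.000116; 0.124 with an estimated correlation). Across genes the Lin28B differences at high and low Myc had a Pearson correlation of 0.141 and the same sign in 54.2%, and those of Myc and of Lin28B, each averaged, one of 0.0722.

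SIT1 was lower at high Myc by 1.15 ± 0.09 in empty-vector cells (signal 957 ± 17 against 2126 ± 39) and differed by -0.11 ± 0.09 with Lin28B (881 ± 42 against 950 ± 93), an interaction of 1.04 ± 0.12 (adjusted p = 0.0295). SIT1 was the only one of 11350 genes that passed, with 613 at an unadjusted p under 0.05 in limma and 568 expected by chance. The count was 0 without array 2 of the empty-vector high-Myc group, either array of the empty-vector low-Myc group, array 1 of the Lin28B high-Myc group or array 2 of the Lin28B low-Myc group. It was 2 without array 1 of the latter, and 3, all lower, relative to the poly-A controls. Among the fits without an array, SIT1 kept its call only without array 1 of the Lin28B low-Myc group, and it lost it with no intensity trend and with poly-A scaling (0.94 to 1.14 over all settings). With the sample number as a block SIT1 lost its call too. The Myc response of MYC was smaller with Lin28B by 0.52 ± 0.12 and did not pass (adjusted p = 0.766). Cholesterol synthesis was the only list called (0.17, adjusted p = 0.0204; 0.578 with an estimated correlation).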

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

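The tests of the poly-A controls, of MYC and of PLSCR1 in this part were chosen after the result had been seen; the splits of the arrays, the interaction and the test of each probe set were not. The 2 groups of 4 arrays, split within each vector or each Myc state, give 18 splits, too few for a share under 0.05. For Myc averaged over both vectors the real split called 8334 genes and the highest other 1, and for Lin28B averaged over both Myc states 24 and 1. The other Myc splits put high- and low-Myc arrays together or set the vectors against each other. With a large Myc difference this leaves few calls by construction.

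The poly-A control RNAs were brighter on the low-Myc arrays by 0.837 (log2), a signal outside the genes compared. Array scaling and hybridization are argued against as the whole source, since the hybridization controls, which pass through both, differed by 0.0976. That mean includes 1 bright high-Myc array with Lin28B (0.336 relative to all arrays), and in empty-vector cells the difference was 0.192. After these are taken off, 0.689 remained in empty-vector and 0.790 in Lin28B cells. Less messenger RNA per total RNA at low Myc and a different amount of control mix for each Myc state predict the same remainder and cannot be told apart, because every low-Myc sample lies on one side. In the poly-A scaling 1166 genes were called lower at high Myc, against 3611 in the deposited one, so that the number of genes that fell stays open.

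MYC was higher with Lin28B at low Myc by 0.734. Leaky repression in those cultures is argued against as a source of more Myc activity: MYC moved by 0.333 of its range between the Myc states, while the slope of all genes along their Myc response was 4.18e-05 (-0.0155 to 0.0124 without each array). This holds only if genes respond in proportion to the MYC signal down to its low-Myc level, which was not tested. The let-7 lists did not rise as a class by as much as MYC, since the median plus SD of members was at most 0.275 in both. A smaller release of let-7 targets is not decided by this, and the arrays gave no check of the vector. A rise of MYC mRNA alone stays open, and so does a difference between the infected and separately selected cell pools, which the design confounds with the vector.

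PLSCR1 was higher with Lin28B by 2.50 over both Myc states. An interferon response as large as this rise is argued against. The median of the 30 interferon-stimulated genes was -0.029 and the median plus SD 0.148. A response much smaller than that of PLSCR1 is not decided by this. A fault of a single probe set is argued against at low Myc, where the other PLSCR1 probe set differed by 2.42. At high Myc that probe set differed by 0.05, and nothing decides there. An effect of Lin28B, a vector insertion near the gene and a difference between the selected pools cannot be separated by this design.

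SIT1 was singled out because its Myc response differed between the vectors in a test of the interaction (1.04). LMBR1 was singled out because its Myc response had opposite signs, 0.43 with empty vector and -0.35 with Lin28B (a difference of -0.775); the interaction test gave an adjusted p of 0.766 for LMBR1. Among 4106 probe sets with no gene listed, which no comparison above used, 2046 (49.8%) changed between the Myc states in empty-vector cells, 618 of them higher at high Myc. Of 22117 probe sets with 1 gene symbol 13159 (59.5%) changed, 6300 of them higher, all in the deposited scaling.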

How the results depend on the processing

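The poly-A scaling was chosen after the data had been seen, all other alternatives before; where no reason follows from the alternative itself, the cause was not tested. The Myc counts in empty-vector cells, in Lin28B cells and in their mean stayed within 1.5 times, except with each probe set tested by itself (15838, 16043 and 18671), where more tests are made, and with a log2 difference of at least 1 (3690, 3779 and 3720), a stricter threshold. Leaving out each array gave 6621 to 7377, 6619 to 7392 and 7958 to 8099. The Lin28B counts were less stable. At high Myc the count of 3 became 0 with a pseudocount at the median, 1 with no filter, 1 with a filter at the 75th percentile, 1 with no intensity trend, 1 with a log2 difference of at least 1, 0 with only the 4 arrays compared, 73 with poly-A scaling and 0 to 7 without each array. At low Myc the count of 6 became 3 with the mean of probe sets, 1 with no intensity trend, 10 with only the 4 arrays compared, 21 with poly-A scaling and 2 to 7 without each array. In the mean the count of 24 became 2 with no intensity trend, 5 with a log2 difference of at least 1, 109 with poly-A scaling and 3 to 21 without each array. The interaction count of 1 became 2 with quantile normalization, 2 with each probe set by itself, 0 with no intensity trend, 3 with poly-A scaling and 0 to 2 without each array. The correlation of the Myc responses of 0.955 became 0.944 with a pseudocount of 1, 0.969 with one at the median, 0.815 with no filter, 0.985 with a filter at the 75th percentile and 0.941 to 0.946 without each array. That of Lin28B at both Myc states became 0.0231 with no filter and 0.102 to 0.134 without each array, and that of Myc with Lin28B 0.026 to 0.114. Leaving an array out leaves its group with 1 array, which is assumed to vary like the other groups.

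With poly-A scaling the means of these called lists reversed: p53 response between the Myc states (0.229), and with Lin28B in the mean ribosome biogenesis (-0.103), established Myc-activated genes (-0.103), mitochondrial biogenesis (-0.107), ribosomal proteins (-0.0569) and p53 response (-0.0571). DDB2 reversed between the Myc states (0.0173). A shift of all genes on an array does this by construction. Of the named genes called between the Myc states in empty-vector cells 117 of 121 kept their call in all settings that include them, and with Lin28B in the mean 1 of 16. With the sample number as a block the Myc counts were 7347, 7425 and, in the mean, 8343. The Lin28B counts were then 2 at high Myc, 6 at low Myc and 23 in the mean, and the interaction count 0. Deviations of arrays with the same number correlated by -0.036 to 0.058, so no large shared shift was seen. That does not show whether the samples were handled in pairs, which the labels do not say. The number of arrays per group limits the precision.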

Other observations

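Plasma cell and germinal centre genes moved apart between the Myc states in empty-vector cells, 8 of 16 higher and 5 lower at high Myc (mean 0.08, adjusted p = 0.602). FKBP11, a folding factor of secretory cells (3.45 ± 0.11), and SDC1, the plasma cell marker CD138 (2.94 ± 0.23), rose, and the germinal centre genes LMO2 (-4.02 ± 0.16) and MYBL1 (-3.42 ± 0.20) fell. Of 10 polyamine genes 4 rose and 3 fell (mean 0.39, adjusted p = 0.469). SRM (8.02-fold), SMS (1.94 ± 0.09), AMD1 (1.93 ± 0.11) and ODC1 (1.63 ± 0.09) rose, and SAT1 (-2.89 ± 0.08), PAOX (-1.44 ± 0.17) and OAZ2 (-0.37 ± 0.11) fell; ODC1, PAOX and OAZ2 were named after their values had been seen. Of 23 adhesion and cytoskeleton genes 18 fell, or 19 when adjusted over the list alone, and ACTN1 rose (2.17 ± 0.21; mean -0.99, adjusted p = 8.54e-06; 0.03 with an estimated correlation). ITGB2 (-2.76 ± 0.11) and ITGAX (-2.20 ± 0.50), integrins of leukocytes, and S100A11 (-2.19 ± 0.11) fell most. The mean of that list relative to the poly-A controls was -0.14.

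Markers of other cell types were few. ITGAM (-3.99 ± 0.11) and LYZ (-3.44 ± 0.18) were the only measured monocyte markers of 15 and both fell at high Myc (mean -3.71). Of 7 T and NK cell markers CD2 (-1.94 ± 0.49), PRF1 (-1.40 ± 0.19) and CD3G (-0.94 ± 0.25) fell (mean -0.76, adjusted p = 0.231; mean 0.05 with poly-A scaling), and CD3G lost its call without array 2 of the empty-vector high-Myc group and with poly-A scaling (-0.14). Among 6 fibroblast and epithelial markers EPCAM rose (2.42 ± 0.16; mean 0.27, adjusted p = 0.721). Common reference genes were not constant: 7 of 13 rose and 2 fell, or 3 when adjusted over the list alone (mean 0.41, adjusted p = 0.153), with HPRT1 (2.00 ± 0.10), TFRC (1.30 ± 0.07), SDHA (0.93 ± 0.08) and TBP (0.88 ± 0.15) higher at high Myc. Over all genes 64.7% changed. Relative to the poly-A controls 12 of the 13 reference genes rose and 0 fell (mean 1.29). Of the published let-7 targets the 7 that also stand in another list had a mean of 1.48 and the 16 that do not had 0.49, with 12 higher and 2 lower. With Lin28B in the mean 1 probe set with no gene listed changed (-0.46, adjusted p = 0.0422).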
